A study of Homo sapiens with 4 samples.

How the data were processed

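RNA was taken from stable 143B cells carrying shFTO or control plasmids. Messenger RNA was enriched on oligo(dT) beads, the second cDNA strand was made with dUTP, and libraries were sequenced on an Illumina HiSeq instrument, per the labels' protocols. The submitters' processing notes name cutadapt, HISAT2 2.0.5, StringTie, STAR 2.5.2b and the genome build hg19, without saying which tool made which value. Whether counting used strand is not given in the sources used here.

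The authors deposited a table of 11972 genes, all protein coding, with an FPKM value per library, per the file headers. The table appears to hold genes whose mean reached 0.5 FPKM in at least 1 group, since the lowest such value was 0.5001. The authors' deposited group columns, although headed FPKM in the file, were recomputed as means of log2(FPKM + 1). The authors' deposited log2 fold change was the difference of these means, and the deposited fold change was 2 to that power. The authors' deposited p-value was recomputed as an equal-variance test on log2(FPKM + 1), and the deposited q-value had been adjusted over 15068 rows, more than the table holds. Between 10 and 13 genes per library were listed at 0, and 7 symbols were carried by 2 rows each.

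Samples were grouped by their titles and treatment labels into shFTO and shCtrl, with 2 libraries each. No pair of libraries held more than 6 identical values, so all 4 were kept as separate libraries. Depth per sample is unknown: in low genes the strongest periodicity of the values was 0.243 to 0.264, below the highest of 20 jittered sets in each library, so whole reads were not recovered and no counting interval was computed.

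The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), a pseudocount of 1, with a mean-variance trend and no block, as fixed before the data were examined. Genes with at least 1 FPKM in at least 2 libraries were tested, 10873 in all, and a Benjamini-Hochberg adjusted p under 0.05 was the threshold. FTO did not meet this filter, so its difference came from the same fit over all 11972 listed genes. Fold changes are on the log2(FPKM + 1) scale and understate the change of low genes. Ratios of mean FPKM are given beside them for FTO and DACT1.

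The 28 gene lists were fixed before the data were examined. Those with at least 5 tested members, 25 of 28, were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. With an estimated correlation 0 of the 5 called lists passed (smallest camera adjusted p = 0.665). That setting also takes its degrees of freedom from the 4 libraries and not from the genes. Its larger p-values therefore cannot be read as an effect of correlation alone. Wnt antagonists had an estimated correlation of -0.0581, below the preset, yet their unadjusted camera p rose from 0.0093 to 0.107. Limma's fry called 0 lists in 1 direction (smallest adjusted p = 0.124) and 11 in either direction. Fry does not compare a list with other genes.

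Named genes followed a rule fixed in advance: FTO, DACT1, the genes past the threshold, and the smallest unadjusted p-values in each direction to make 10 higher and 10 lower, stated as not passing. Of the genes this rule selected, 1 is not reported here. No list had a member past the main threshold. The list members named because they passed when adjusted over the list alone, and others named for their known function, were chosen after their values were seen. Coordinates are those of the deposited table (hg19, per the submitters' processing notes). Transcript lengths and GC content came from GENCODE release 29 by gene ID, with 99.6% of IDs matched, and no coordinates were taken from it. Of the listed genes, 850 overlap another listed gene on the same strand, and their values are uncertain where reads could be divided between them.

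The procedure was tested on simulated data for the comparison of shFTO with shCtrl, in 20 sets of 10873 genes with 200 changed. Limma recovered 30.1% of genes changed by 1 on the log2 scale, 94.2% of those changed by 2 and 98.3% of those changed by 3. Of all calls, 5.9% were false. The changed genes lay above a minimum mean level that FTO and DACT1 did not reach, with equal spread in both groups. These rates therefore do not give the share of real changes detected. In the data ANKRD1 changed by -3.08 (limma adjusted p = 0.104) and BCL2L2 by -2.68 (0.0964), and neither passed. A list shifted by 0.5 was called in 100% of sets and an unshifted list in 0%. The simulated genes varied independently, whereas the estimated correlation was 0.757 for oxidative phosphorylation and 0.152 for NF-kB and cytokines. The 0% therefore does not carry over to lists whose members vary together. Alternatives covered the pseudocount (0.1), the filter (none, or a mean of at least 5 FPKM), quantile and median-ratio scaling, the variance model, a replicate block, leaving out each library, an unadjusted p with a 2-fold change, and an estimated correlation for the lists. Leaving out genes that overlap another listed gene on the same strand was added after seeing the data. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the checks, resampling and figures.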

Results

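Gene expression was measured by RNA sequencing in 143B cells, a human osteosarcoma line, after stable knockdown of FTO. FTO encodes a demethylase that removes the methyl group from N6-methyladenosine (m6A) in RNA. The 4 libraries fell into 2 groups of 2: cells carrying a short hairpin RNA against FTO (shFTO) and cells carrying a control hairpin (shCtrl). The deposited values were fragments per kilobase of transcript, scaled to each library's mapped fragments (FPKM), of 11972 protein-coding genes, which summed to between 200555 and 212531 per library. Between 10587 and 10813 of these genes reached 1 FPKM in a library. Read depth was unknown, because FPKM carry no counts and their low values showed no steps of whole reads. Nothing in the labels said that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Across genes, the 2 shFTO libraries correlated with each other at r = 0.964 on the log2 scale, and the 2 shCtrl libraries at r = 0.983. The shFTO libraries correlated with the shCtrl libraries at r = 0.961 to 0.973, a range that holds the value of the shFTO pair.

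The first question was whether the targeted transcript was lower in the libraries labelled as knockdown. FTO (chromosome 16, 53735604 to 54192424, plus strand, hg19) was lower in both shFTO libraries than in both shCtrl libraries, at 0.268 and 0.242 FPKM against 1.14 and 0.665 FPKM. Its mean was 0.255 ± 0.018 FPKM (SD, n = 2) in shFTO and 0.902 ± 0.336 FPKM (SD, n = 2) in shCtrl, 71.7% lower. FTO stayed below the expression minimum of the main test, so its difference was taken from a fit over all 11972 listed genes, where it was -0.59 on the log2(FPKM + 1) scale (SE 0.16, 95% confidence interval -0.98 to -0.20, limma adjusted p = 0.313). The difference did not pass the threshold, and this scale understates the change of a gene at so low a level. With a pseudocount of 0.1 the difference was -1.46 and still did not pass (limma adjusted p = 0.298). Its size leaned on the shCtrl libraries, at -0.41 without shCtrl replicate 1 and -0.77 without shCtrl replicate 2. In the authors' deposited table FTO had p = 0.0834 and q = 0.603.

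DACT1, which encodes an antagonist of Wnt signalling and is the gene that the study's title names, was higher in both shFTO libraries, at 1.61 and 2.06 FPKM against 0.154 and 0.595 FPKM in the shCtrl libraries. Its mean was 1.84 ± 0.32 FPKM (SD, n = 2) in shFTO and 0.375 ± 0.312 FPKM (SD, n = 2) in shCtrl, a ratio of 4.9 that rests on low and spread shCtrl values. The gene lies on chromosome 14, 59100685 to 59115039 (hg19). The difference was 1.06 on the log2(FPKM + 1) scale (SE 0.20, 95% confidence interval 0.56 to 1.55) and did not pass over all genes tested (limma adjusted p = 0.206). It passed when adjusted over the list of Wnt antagonists alone (limma adjusted p = 0.0179), which is not independent evidence because the study had singled out DACT1. With a pseudocount of 0.1 the log2 difference was 2.19 and did not pass (limma adjusted p = 0.288). The difference was 1.17 without shFTO replicate 1, 0.94 without shFTO replicate 2, 0.82 without shCtrl replicate 1 and 1.29 without shCtrl replicate 2. Of these fits only that without shFTO replicate 1 passed, where the lone shFTO library is assumed to vary like the shCtrl pair. In the authors' deposited table DACT1 had p = 0.0555 and q = 0.554.

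**Figure D1:**
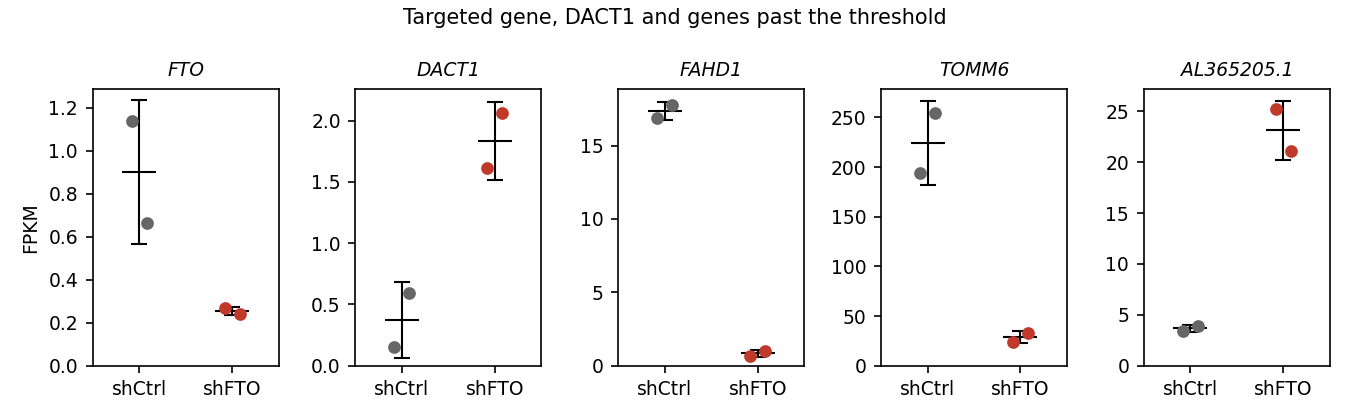
Expression in FPKM (vertical axes, each starting at 0 with its own range) of FTO, DACT1 and the 3 genes past the threshold, by group; dots are libraries, and black bars give the mean and SD of 2 libraries. FTO lay at 0.242 to 0.268 FPKM in shFTO and 0.665 to 1.14 FPKM in shCtrl, and in none of the 5 genes did the groups overlap.

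The next comparison asked which genes differed between shFTO and shCtrl cells. FAHD1, which encodes a mitochondrial acylpyruvase and oxaloacetate decarboxylase, fell from 17.4 ± 0.578 FPKM in shCtrl to 0.833 ± 0.266 FPKM in shFTO (SD, n = 2 each). TOMM6, a small subunit of the translocase that imports proteins into mitochondria, fell from 224 ± 42 to 28.6 ± 6.27 FPKM (SD, n = 2 each). AL365205.1, a gene known by its clone name, rose from 3.67 ± 0.368 to 23.1 ± 2.94 FPKM (SD, n = 2 each). These 3 genes were the ones that passed among 10873 tested.

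FAHD1 (chromosome 16, 1876942 to 1890208, hg19) changed by -3.33 on the log2(FPKM + 1) scale (SE 0.18, limma adjusted p = 0.022). TOMM6 (chromosome 6, 41755400 to 41757636) changed by -2.93 (SE 0.21, limma adjusted p = 0.0433) and AL365205.1 (chromosome 6, 41748087 to 41757879) by 2.37 (SE 0.17, limma adjusted p = 0.0433). TOMM6 lies inside AL365205.1 on the same strand, so reads could be divided between these genes and both values are uncertain. Before adjustment limma gave 1180 genes an unadjusted p under 0.05, 773 of them higher and 407 lower in shFTO, where 544 were expected with no effect. This split was 619 higher and 489 lower with quantile normalization, and 652 and 508 with median-ratio scaling. The groups did not overlap for 4635 tested genes (42.6%), against 33.3% by chance. The 544 and the 33.3% are averages, and with 4 libraries genes that vary together can move both counts away from them. Neither excess therefore measures how many genes differed. An exact two-sided permutation test of a single gene cannot go below 0.333 in this design. The authors' deposited table held 1107 genes with p under 0.05, of which 38 were at least 2-fold higher and 26 at least 2-fold lower in shFTO, and 0 with q under 0.05 (smallest q 0.08).

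The genes with the smallest p-values among those that did not pass are given as values. In the higher direction, the chemokine gene CXCL1 had 13.5 ± 0.728 FPKM in shFTO and 2.97 ± 0.285 FPKM in shCtrl (SD, n = 2 each). ESM1, which encodes the secreted proteoglycan endocan, had 145 ± 19.2 against 47.5 ± 2.22 FPKM (SD, n = 2 each). TGFBR1, the type I receptor for TGF-beta, had 10.9 ± 0.273 against 2.98 ± 0.371 FPKM, and the Wnt receptor gene FZD6 had 17.2 ± 2.27 against 5.51 ± 0.457 FPKM. The mitochondrial peroxidase gene PRDX3 had 88.9 ± 2.36 against 36.5 ± 1.28 FPKM, and UNC13A, which encodes a protein of synaptic vesicle release, had 4.98 ± 0.0971 against 0.97 ± 0.0971 FPKM. RNF4 and UBALD1 had means of 10.4 and 5.85 FPKM in shFTO and 2.77 and 1.83 FPKM in shCtrl. RNF4 overlaps another listed gene on its strand.

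In the lower direction, ANKRD1, a target of the coactivator YAP, had 15.6 ± 9.02 FPKM in shFTO and 129 ± 9.89 FPKM in shCtrl (SD, n = 2 each). The imprinted gene MEST had 1.64 ± 0.165 against 8.2 ± 0.038 FPKM, and IGFBP1, which encodes a binding protein of insulin-like growth factors, had 0.425 ± 0.292 against 3.39 ± 0.201 FPKM. BCL2L2, an anti-apoptotic member of the BCL2 family, had 1.55 ± 1.08 against 14.5 ± 0.452 FPKM, and it overlaps a listed read-through gene on its strand. GALNT3, which starts mucin-type O-glycosylation, had 0.821 ± 0.0902 against 4.17 ± 0.649 FPKM. PLAC8, GPRC5A and SPX had means of 2.64, 3.35 and 1.56 FPKM in shFTO and 10.7, 10.7 and 4.94 FPKM in shCtrl. All 16 of these genes failed the correction, with limma adjusted p up to 0.104.

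The number of calls moved with the library left out. Without shFTO replicate 1 limma called 429 genes and without shFTO replicate 2 it called 217, whereas without shCtrl replicate 1 or 2 it called 0 (509 and 584 genes at unadjusted p under 0.05). With quantile normalization 2 genes passed, 0 higher and 2 lower, with median-ratio scaling 1 gene passed, which was lower, and with a pseudocount of 0.1 it was 0 (1167 at unadjusted p under 0.05).

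Gene groups fixed before the data were examined were then compared. Genes of the NF-kB pathway and inflammatory cytokines were higher in shFTO: 16 of 18 tested members lay above shCtrl, with a median difference of 0.64 on the log2(FPKM + 1) scale (limma camera adjusted p = 3.57e-06). With an estimated correlation the limma camera adjusted p was 0.665, a setting that also takes its degrees of freedom from the 4 libraries. The members that passed when adjusted over the list alone were CXCL1, CXCL2, CXCL3, CSF3, IL1B, PTGS2 and RELB, all higher. The chemokine genes CXCL2 and CXCL3 had 2.24 ± 0.273 and 2.06 ± 0.0519 FPKM in shFTO and 0.926 ± 0.265 and 0.464 ± 0.316 FPKM in shCtrl (SD, n = 2 each). CSF3, which encodes the granulocyte growth factor, had 3.11 ± 0.942 against 0.599 ± 0.171 FPKM, and the cytokine gene IL1B had 2.34 ± 1.05 against 0.393 ± 0.0161 FPKM. PTGS2, which encodes an inducible enzyme of prostaglandin synthesis, had 2.78 ± 1.04 against 1 ± 0.095 FPKM. The NF-kB subunit gene NFKB1 and the feedback inhibitor gene TNFAIP3 differed by 0.05 and 0.10 on the log2 scale and did not pass. Without shFTO replicate 1 the list's median was 0.29 (limma camera adjusted p = 0.00824).

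Wnt antagonists were also higher in shFTO, with 12 of 17 tested members above shCtrl and a median difference of 0.42 (limma camera adjusted p = 0.0465, and adjusted p = 0.665 with an estimated correlation). This list holds DACT1, which the study had chosen, and so is not independent evidence of its direction. The adjusted p was 0.329 without shFTO replicate 2 (median 0.27), 0.121 without shCtrl replicate 2, 0.0554 with a pseudocount of 0.1 and 0.428 among genes with a mean of at least 5 FPKM. Without shCtrl replicate 1 the median was 0.24 (limma camera adjusted p = 0.0178). CTNNBIP1, which encodes an inhibitor of the binding of beta-catenin to TCF factors, passed when adjusted over the list alone, with 7.24 ± 0.643 FPKM in shFTO and 2.76 ± 0.631 FPKM in shCtrl (SD, n = 2 each). KREMEN1, a receptor for DKK proteins, and the secreted antagonist SFRP1 also passed over the list alone, at 1.9 ± 0.134 against 0.905 ± 0.0195 FPKM and 34.4 ± 0.829 against 23.5 ± 0.488 FPKM. The secreted antagonist DKK1 lay in the opposite direction and did not pass, at 23.5 ± 21.2 against 58.6 ± 6.6 FPKM. Among Wnt ligands, receptors and transducers, 20 of 28 tested members were above shCtrl (limma camera adjusted p = 0.161), and the receptor genes FZD6 and FZD8 passed over the list alone as higher. The receptor genes FZD7 and FZD2 lay in the opposite direction and did not pass, at 6.09 ± 0.742 against 9.87 ± 0.0578 FPKM and 6.39 ± 2.2 against 11.6 ± 1.96 FPKM. Targets of Wnt and beta-catenin did not pass as a list (14 of 23 above shCtrl, median 0.07, limma camera adjusted p = 0.364), and 0 of them passed over the list alone. When 1 library was left out, their median ran from 0.03 without shCtrl replicate 2 to 0.16 without shFTO replicate 1. It was 0.01 among genes with a mean of at least 5 FPKM and 0.02 with quantile normalization. For change in either direction limma's fry gave an adjusted p of 0.00194, but 11 of the 25 tested lists passed this test. Fry does not compare a list with other genes, so this is not particular to Wnt targets. At an unadjusted limma p under 0.05, 4 target genes were higher and 2 lower, none of which passed the correction. MYC, TNFRSF19, VEGFA and JUN differed by 1.06, 0.78, 0.55 and 0.48 on the log2 scale. DKK1, which is also in the list of antagonists, differed by -1.62 and BIRC5 by -0.48. MYC had 4.18 ± 0.466 FPKM in shFTO against spread shCtrl values of 1.73 ± 1.58 FPKM. LEF1 and CCND1, both used as Wnt readouts, had 4.28 ± 0.291 against 4.07 ± 0.14 FPKM and 158 ± 17.6 against 159 ± 5.49 FPKM.

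Extracellular matrix genes and matrix proteases were higher, with 21 of 27 tested members above shCtrl and a median difference of 0.29 (limma camera adjusted p = 0.0465). The adjusted p was 0.665 with an estimated correlation, 0.0525 with a pseudocount of 0.1 and 0.309 without shCtrl replicate 2. MMP14, a membrane-bound matrix metalloproteinase, passed over the list alone with 21.5 ± 3.93 FPKM in shFTO and 7.39 ± 0.466 FPKM in shCtrl (SD, n = 2 each). The collagenase gene MMP1 reached 297 and 1414 FPKM in the shFTO libraries and 159 and 170 FPKM in the shCtrl libraries. Of 26 tested EMT and mesenchymal genes, 17 were above shCtrl (limma camera adjusted p = 0.364), and fibronectin (FN1) passed over the list alone at 66 ± 32.5 against 10.7 ± 2.18 FPKM.

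Genes of G2/M and mitosis were lower in shFTO: 24 of 30 tested members lay below shCtrl, with a median difference of -0.13 (limma camera adjusted p = 0.00125, and adjusted p = 0.665 with an estimated correlation). Without shCtrl replicate 2 the median was -0.20 (limma camera adjusted p = 0.000797). CDC20, an activator of the anaphase-promoting complex, had 132 ± 20.6 FPKM in shFTO and 193 ± 16.3 FPKM in shCtrl (SD, n = 2 each), and the kinase gene PLK1 had 19.8 ± 1.46 against 25.5 ± 1.09 FPKM. None of the 30 passed over the list alone. G1/S and DNA replication genes did not pass as a list (median -0.02, 0.01 with quantile normalization, limma camera adjusted p = 0.411).

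Nuclear genes of oxidative phosphorylation were lower, with 24 of 30 tested members below shCtrl and a median difference of -0.16 (limma camera adjusted p = 0.00953). The adjusted p was 0.702 with an estimated correlation, 0.159 with quantile normalization, 0.653 without shFTO replicate 2 and 0.488 without shCtrl replicate 2, the last 2 with a median of -0.02. The succinate dehydrogenase gene SDHB had 48.1 ± 6.66 FPKM in shFTO and 61.2 ± 3.76 FPKM in shCtrl (SD, n = 2 each), and none of the members passed over the list alone. Mitochondrially encoded transcripts, which took 17.1% and 14.4% of summed FPKM in the shFTO libraries and 14.7% and 14% in the shCtrl libraries, did not pass (median 0.08, limma camera adjusted p = 0.219). Their median was -0.15 without shFTO replicate 1, and without shFTO replicate 2 it was 0.26 and the list passed (limma camera adjusted p = 0.000554).

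**Figure D2:**
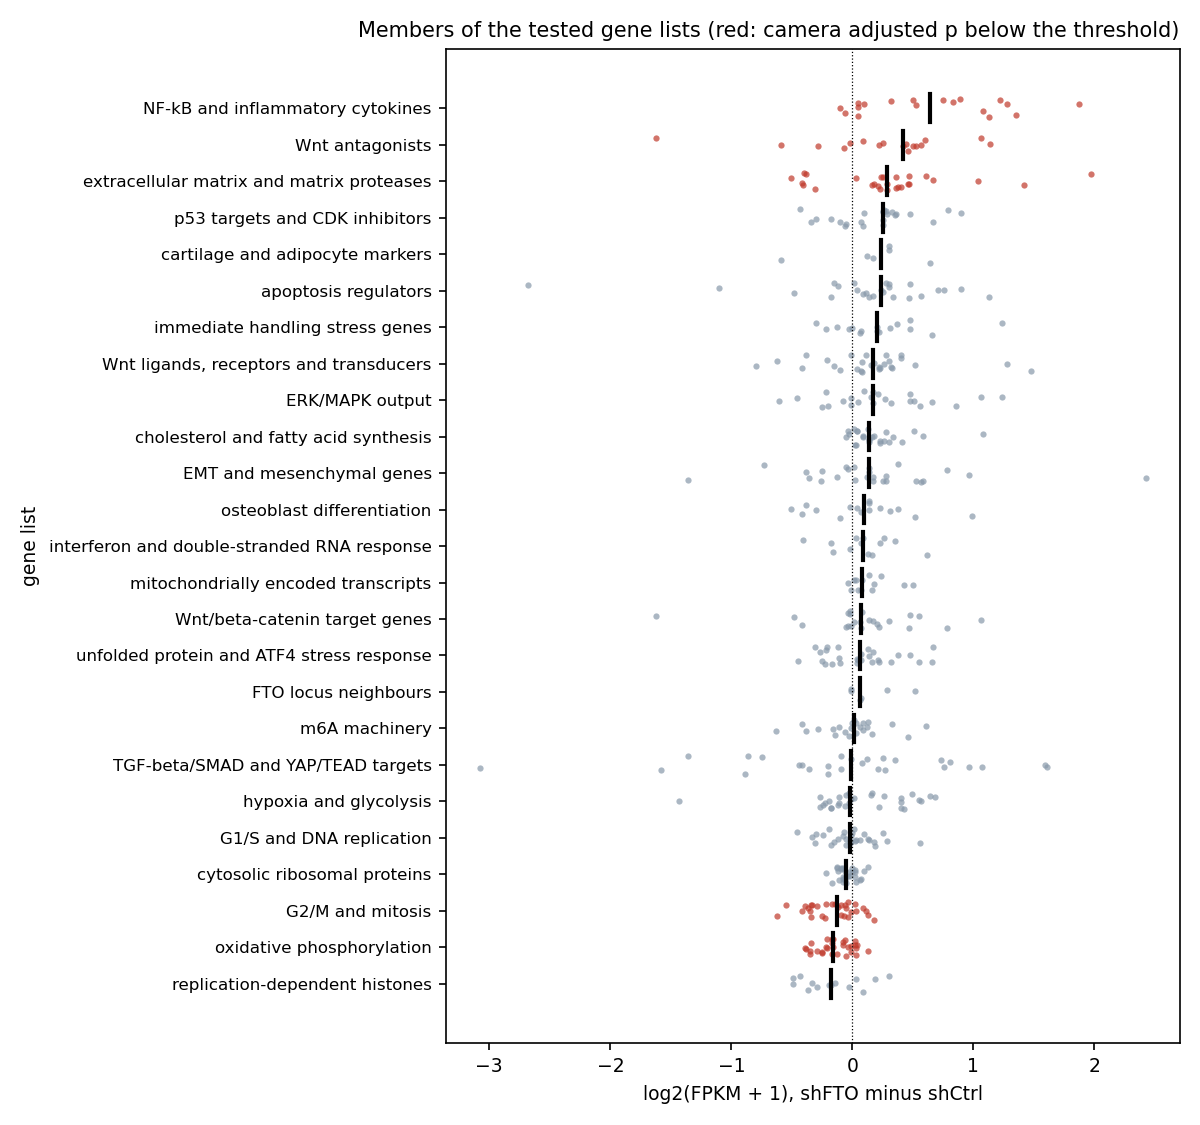
Difference in log2(FPKM + 1), shFTO minus shCtrl (horizontal axis), for each tested member (dot) of the 25 tested gene lists (vertical axis), with the median as a black bar and lists past the threshold of limma's camera in red. The medians ran from 0.64 for NF-kB and inflammatory cytokines to -0.18 for replication-dependent histones, and the 5 red lists did not pass with an estimated correlation.

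The list of TGF-beta/SMAD and YAP/TEAD genes held members at both ends of the scale. Of its 27 tested members, 7 were higher and 6 lower when adjusted over the list alone, and as a list they did not pass (median -0.01, limma camera adjusted p = 0.586). Leaving out 1 library gave medians from -0.21, without shFTO replicate 1, to 0.01, without shCtrl replicate 2. The receptor genes TGFBR1 and TGFBR2, PMEPA1, which is induced by TGF-beta, LTBP2, SKIL, ACTA2 and INHBA were the members that were higher. PMEPA1 had 6.85 ± 0.954 FPKM in shFTO and 2.73 ± 0.0289 FPKM in shCtrl (SD, n = 2 each), and TGFBR2 had 63 ± 17.5 against 36 ± 1.52 FPKM. The lower members were ANKRD1, CTGF, AJUBA, TGFB2, AXL and CRIM1, of which CTGF (connective tissue growth factor) had 147 ± 2.45 against 248 ± 2.66 FPKM. AJUBA overlaps another listed gene on its strand. Limma's fry, which asks whether members change in either direction, gave an adjusted p of 0.0186 for this list. It was among 11 lists that passed this test, which does not compare a list with other genes.

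**Figure D3:**
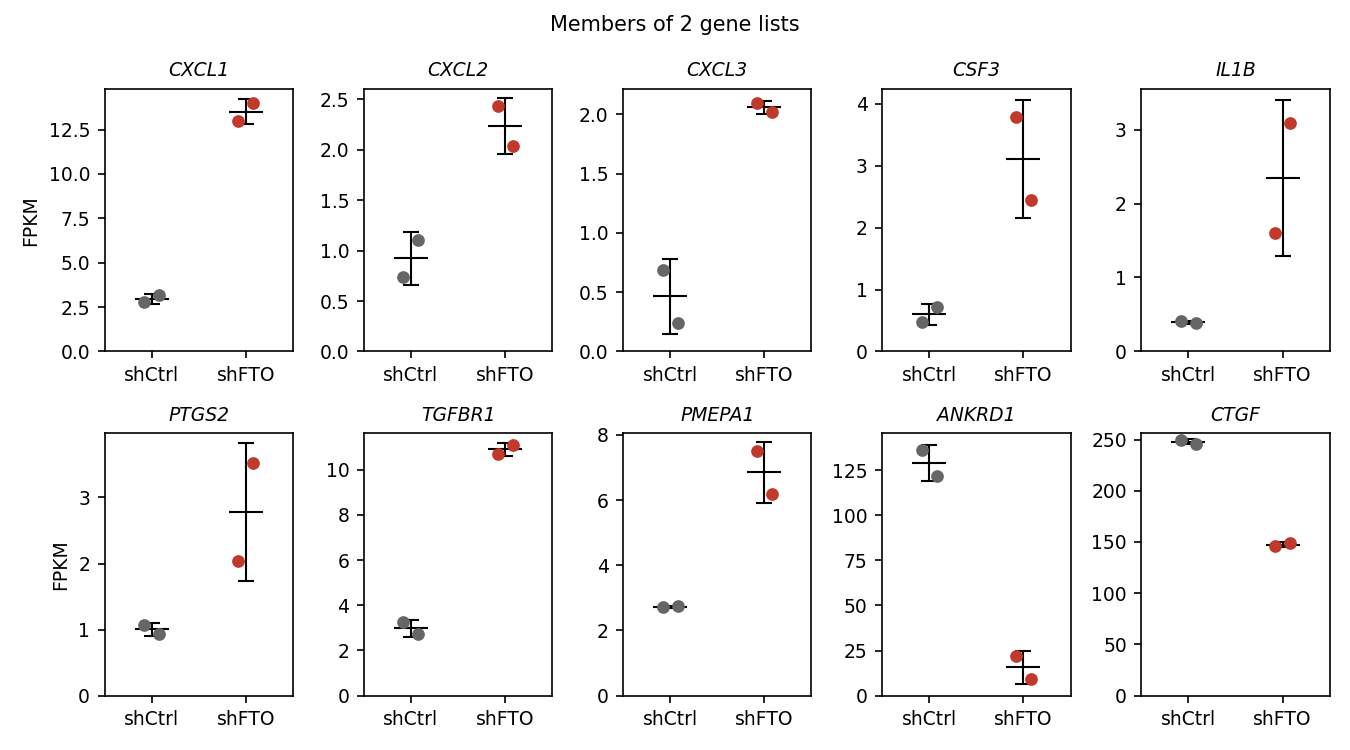
Expression in FPKM (vertical axes from 0, each with its own range) of 6 members of the NF-kB and cytokine list and 4 of the TGF-beta/SMAD and YAP/TEAD list, by group; dots are libraries, and black bars give the mean and SD of 2 libraries. CXCL1 had a mean of 13.5 FPKM in shFTO and 2.97 FPKM in shCtrl, and ANKRD1 15.6 and 129 FPKM.

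Other signalling and survival lists did not pass in the main test. ERK/MAPK output genes had 16 of 24 tested members above shCtrl (limma camera adjusted p = 0.0967, and 0.0184 with quantile normalization), and adjusted over the list alone EGR1 and DUSP6 were higher and PHLDA1 was lower. EGR1, an immediate early transcription factor, had 10.8 ± 0.451 FPKM in shFTO and 4 ± 0.212 FPKM in shCtrl (SD, n = 2 each). Apoptosis regulators had 19 of 25 above shCtrl (limma camera adjusted p = 0.197), while the anti-apoptotic genes BCL2L2 and BCL2L1 were lower when adjusted over the list alone, the second at 15.4 ± 1.02 against 34.1 ± 2.07 FPKM. The p53 targets and CDK inhibitors had 17 of 24 above shCtrl (limma camera adjusted p = 0.0967, and 0.0113 without shFTO replicate 1), with CDKN1A at 7.84 and 30.3 FPKM in the shFTO libraries and 7.74 and 9.63 FPKM in the shCtrl libraries.

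Genes of the m6A machinery did not pass as a list (13 of 23 above shCtrl, median 0.01 although camera's direction was down, limma camera adjusted p = 0.717). The demethylase gene ALKBH5 had 27.2 ± 1.23 FPKM in shFTO and 25.1 ± 3.24 FPKM in shCtrl, and the methyltransferase gene METTL3 had 9.11 ± 0.184 against 8.48 ± 0.0595 FPKM (SD, n = 2 each). The neighbours of FTO on chromosome 16 had a limma camera adjusted p of 0.411, with IRX3 at 6.24 ± 0.773 against 5.91 ± 0.459 FPKM. Osteoblast differentiation genes, which mark the bone-forming lineage, had 10 of 16 tested members above shCtrl (limma camera adjusted p = 0.747), with SPP1 at 5.99 ± 2.26 against 5.68 ± 1.25 FPKM.

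Among stress and metabolic lists, interferon and double-stranded RNA response genes had a median difference of 0.09 over 13 tested members (0.03 without shFTO replicate 1 and 0.04 without shFTO replicate 2, limma camera adjusted p = 0.549), with ISG15 at 12.6 ± 0.533 FPKM in shFTO and 12.1 ± 2.77 FPKM in shCtrl (SD, n = 2 each). Unfolded protein and ATF4 stress genes had a median of 0.06 (adjusted p = 0.514; the median was 0.03 without shCtrl replicate 2, 0.13 with quantile normalization and 0.02 with median-ratio scaling), and hypoxia and glycolysis genes a median of -0.02 against a mean of 0.06 and an upward direction in camera (adjusted p = 0.517), both by limma's camera. Cholesterol and fatty acid synthesis genes had 23 of 26 members above shCtrl (median 0.14, limma camera adjusted p = 0.0967). Their median was -0.06 without shFTO replicate 2, and the list passed without shFTO replicate 1 (median 0.42, limma camera adjusted p = 1.1e-05) and with quantile normalization (adjusted p = 0.03). Immediate handling stress genes had 12 of 16 above shCtrl, EGR1 among them (limma camera adjusted p = 0.0967, but 0.0184 with quantile normalization and 0.0283 without shCtrl replicate 2). Replication-dependent histones had a median of -0.18 (0.16 without shFTO replicate 2, limma camera adjusted p = 0.0967), and ribosomal proteins one of -0.05 (0.01 with quantile normalization, limma camera adjusted p = 0.21). Both lists passed as lower without shFTO replicate 1 (limma camera adjusted p = 6.16e-05 and 0.00819) and without shCtrl replicate 1 (0.0178 and 0.0066).

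Markers of other cell types were few. The 4 tested epithelial markers, KRT8, KRT18, OCLN and EPCAM, were all lower in shFTO and did not pass, with KRT18 at 119 ± 12.6 FPKM in shFTO and 156 ± 9.74 FPKM in shCtrl (SD, n = 2 each). Of the haematopoietic markers 2 were tested, CD68 at 19.6 ± 8.8 against 12.6 ± 1.06 FPKM and LYZ at 1.09 ± 0.206 against 1.3 ± 0.0887 FPKM. The 4 tested endothelial and neural markers had a median difference of -0.05, and these 3 lists had too few members for a test. Cartilage and adipocyte markers had 5 of 6 tested members above shCtrl (limma camera adjusted p = 0.366), and CEBPB passed over the list alone at 37.5 ± 0.835 against 23.8 ± 3.56 FPKM.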

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

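The alternative that left out overlapping genes was chosen after seeing the data, and all others were planned. The number of genes past the threshold was 3. It was 0 with a pseudocount of 0.1 (1167 at an unadjusted p under 0.05), 1 with no filter on low values, 1 with median-ratio scaling, 1 without the mean-variance trend, 1 without genes that overlap another listed gene on the same strand, and 116 at an unadjusted p under 0.05 with a 2-fold change. Leaving out 1 library gave 0 to 429 genes: 429 without shFTO replicate 1, 217 without shFTO replicate 2, and 0 without either shCtrl library. The remaining lone library is then assumed to vary like the other group. The spread between the shFTO libraries (SD of their log2 deviations from the group mean 0.211) exceeded that between the shCtrl libraries (0.148). FAHD1 lost its call with a pseudocount of 0.1 (limma adjusted p = 0.0502) and without either shCtrl library, over a range of 0.000229 to 0.258 for its alternatives, and for these losses the cause was not tested. TOMM6 lost its call in 6 alternatives (adjusted p up to 0.258) and AL365205.1 in 7 (up to 0.437), with 0.0507 for both under median-ratio scaling. The genes named kept their direction in all 250 combinations of gene and alternative. The naming rule largely fixed this, since it required groups that do not overlap, whose order leaving out 1 library cannot reverse. In 192 combinations the gene stayed on the same side of the threshold, in 16 it lost and in 42 it gained the call.

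FTO stayed lower (-0.41 to -1.46) and never passed. It has no value under the stricter filter. DACT1 stayed higher, and leaving out 1 library gave 0.82 to 1.29. It passed only without shFTO replicate 1 (1.17), where the lone shFTO library is assumed to vary like the shCtrl pair. The cause was not tested. The number of lists past the threshold was 5. It was 3 with a pseudocount of 0.1 and 0 with an estimated correlation (smallest adjusted p = 0.665), while leaving out 1 library gave 3 to 9. Robust variance was not run for lists, as camera has no such option.

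With the replicate number as a block 15 genes passed, 7 higher and 8 lower, including the 3 main calls, and 5 lists passed. Same-numbered libraries deviated from their group means with r = -0.192 across genes, and the labels do not say that a number marks a shared day or culture, so no pairing was assumed.

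Camera's direction turned in 14 of 323 combinations of list and alternative, all in lists that were not called; the values here are medians. With a mean of at least 5 FPKM these were the m6A machinery (0.03) and hypoxia (-0.05), and with quantile normalization the m6A machinery (0.04), G1/S (0.01) and ribosomal proteins (0.01). The others turned when 1 library was left out. The medians then ran from -0.03 to 0.04 for the m6A machinery, 0.07 to 0.14 for osteoblast genes, -0.08 to 0.09 for hypoxia, -0.06 to 0.42 for cholesterol synthesis, -0.15 to 0.26 for mitochondrial transcripts, -0.17 to 0.07 for ribosomal proteins (0.05 without shFTO replicate 2) and -0.39 to 0.16 for histones. The cause was not tested.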

Other observations

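The tests of overlapping genes, of length and GC content, of the interferon list against the cytokine list, of cell density and of the YAP/TEAD split were chosen after the result they bear on was seen. Several well-known genes differed between the 2 shFTO libraries while the 2 shCtrl libraries lay close together, and they were named after their values were seen. They were picked for close shCtrl values, a mean of at least 5 FPKM and no same-strand overlap, so the close shCtrl values are not a finding. Some genes outside this choice also differed between the shCtrl libraries. MED29 had 1.08 and 13.6 FPKM in the shFTO libraries and 9.04 and 1.41 FPKM in the shCtrl libraries. TAGLN, a smooth muscle actin-binding protein, had 12.9 and 2 FPKM in shFTO replicates 1 and 2, and 14.7 and 16.5 FPKM in the shCtrl libraries. The cytokine gene IL1A had 16.2 and 3.2 FPKM against 2.63 and 2.37 FPKM, and the Wnt antagonist DKK1 had 8.5 and 38.5 FPKM against 53.9 and 63.2 FPKM. CDKN1A, which encodes the CDK inhibitor p21, had 7.84 and 30.3 FPKM against 7.74 and 9.63 FPKM, and EFEMP1, a matrix glycoprotein, had 11.8 and 42 FPKM against 16.3 and 15.4 FPKM. Of the 100 tested genes that differed most between the shFTO libraries, 29 overlapped another listed gene on the same strand, against 6.44% of the other 10773 tested genes (two-sided Fisher's exact p = 5.7e-12, with genes not independent). TEAD1, which encodes a DNA-binding partner of YAP, had 18.2 ± 5.85 FPKM in shFTO and 3.49 ± 0.468 FPKM in shCtrl (SD, n = 2 each) and did not pass (limma adjusted p = 0.104).

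TOMM6 fell while AL365205.1, which contains it on the same strand, rose. A candidate explanation is that reads were divided differently between these genes in the groups. Weighted by median transcript length, AL365205.1 took 83.7% and 75.9% of the pair's summed FPKM in the shFTO libraries and 7.97% and 7.1% in the shCtrl libraries, and the sum itself had a ratio of 0.59 (shFTO over shCtrl) where TOMM6 alone had 0.128. A shift of reads alone would leave the sum unchanged only if these lengths were those behind the deposited FPKM, which is not known. A loss of TOMM6 alone would leave AL365205.1 unchanged. Division of reads and a difference in transcription therefore cannot be told apart without reads. Across 352 same-strand overlapping pairs, differences between the 2 shCtrl libraries correlated at r = -0.23 (Spearman -0.06), against 0.13 (Spearman 0.20) across 1199 opposite-strand pairs, where pairs are not independent.

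The NF-kB and cytokine list was higher in shFTO, with a median of 0.64 (95% bootstrap interval over its genes 0.10 to 1.11). Against a bias of gene length or GC content as its whole cause, the median after a linear correction for both was still 0.64 (0.10 to 1.07), and the correction had an SD of 0.050 over genes. An interferon response to the hairpin is another candidate. Both groups carried a hairpin, so the response would have to be stronger to the hairpin against FTO. The interferon list had a median of 0.09 (-0.02 to 0.23). This was 0.03 and 0.04 without shFTO replicates 1 and 2, and 0.09 and 0.12 without shCtrl replicates 1 and 2. Of its 13 tested members, 0 had an unadjusted limma p under 0.05. The interferon median lay below the cytokine list's median, but the 2 intervals overlapped. For these 13 genes the values argue against a response as large as the cytokine median. A smaller one stays open. The bootstrap drew genes as if independent, so these intervals do not measure the spread between libraries. Leaving out shFTO replicate 1 or 2 gave cytokine medians of 0.29 and 0.8. An effect of the FTO knockdown is also open and was not tested, since the group is the knockdown and 2 libraries per group cannot separate it from a difference between cultures.

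Within the TGF-beta/SMAD and YAP/TEAD list, the 11 YAP/TEAD targets had a mean difference of -0.61 (8 lower) and the 16 TGF-beta/SMAD genes one of 0.33 (10 higher). Genes were assigned to these parts by hand after the values were seen, and the TGF-beta/SMAD part holds receptor genes beside targets. The permutation p of 0.0108 (two-sided, 100000 permutations of the 27 genes, difference -0.94) therefore bears only on a hypothesis that these parts may move apart. It leans on ANKRD1 and on AJUBA, which overlaps another gene: without ANKRD1 the YAP/TEAD mean was -0.37 (permutation p = 0.0297), and without both it was -0.23 (permutation p = 0.0707). A linear correction for length and GC content, with an SD of 0.050 over genes, left the difference at -0.95. This argues against a linear bias of that kind across genes as its whole cause, and no other form of bias was tested. Cell density at harvest could lower YAP/TEAD targets together with cycling genes, and it stays open. The S-phase list had a median of -0.02 (bootstrap interval over genes -0.08 to 0.02) and the mitotic list one of -0.13 (-0.27 to -0.05). These intervals do not measure the spread between libraries.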
